A study of Mus musculus with 6 samples.

How the data were processed

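RNA was measured in 6 libraries of primary mouse muscle satellite cells, 3 treated with rhMG53 and 3 with BSA for 72 h, given as day 3 for all libraries in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, checked on a Bioanalyzer and made into libraries with a directional kit after poly(A) selection, following a low-input protocol. Per the submitters' processing notes the genome build was mm10 and the tools included STAR, featureCounts and edgeR, with no versions. The annotation, the strand setting, the treatment of reads that map to several places and any filters are not given in the sources used here. The authors deposited whole-number counts per gene and library, not normalised, in a table of 27179 rows named by NCBI gene ID. All rows name a gene, 6829 rows were 0 in every library, and no column was left unused. Because the strand setting is not given, genes that overlap on opposite strands cannot be separated with certainty. Near-identical copies can also share reads.

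Gene IDs were matched to symbols through a RefSeq gene table of GRCm38.p6, the assembly of mm10, which named 25275 IDs, and through a GENCODE table of Entrez IDs, which named 18 more. The 1886 IDs left without a symbol held 0.509% to 1.26% of the counts of a library and stayed in the tests. Coordinates are 1-based and come from the RefSeq table. Symbols of mitochondrial genes were written in the mouse form.

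Libraries were grouped by their treatment label. The replicate numbers of the labels do not state a shared animal, culture or day, so the fit had treatment as its only term. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13769, and scaled with TMM factors. Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, without robust moderation), 2-sided, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05 on the adjusted p. The SE of a log2 fold change is its size divided by the square root of F, and 95% intervals use the total degrees of freedom of the test. The biological coefficient of variation was 7.89%. CPM values use the TMM-scaled library sizes for single genes. Plain library totals were used for list sums, for Xist and Ddx3y and for unnamed gene IDs. SD values are over the 3 libraries of a group.

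The design, the 33 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists cover satellite cell identity, myogenic commitment, the sarcomere, cell cycle, senescence, stress, inflammation, matrix, metabolism and membrane repair, and markers of other cell types. Lists with at least 5 kept genes, 32 in all, were tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, 2-sided, with adjustment over the 32 lists. Each list was also counted with p-values adjusted over the list alone. Library measures were compared by an exact 2-sided permutation test of the difference of means, for which 3 against 3 cannot give a p below 0.1, with adjusted values of 0.6 for all measures.

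Named genes are Trim72, a panel of 10 genes (Pax7, Myf5, Myod1, Myog, Myh3, Mki67, Cdkn1a, Cdkn2a, Col1a1, Irs1), the called genes with a mean of at least 5 CPM, a named symbol and groups that do not overlap, up to the 10 largest changes in each direction, the 4 members with the smallest p of each list past the threshold, and the 2 members with the smallest p of any other list with at least 3 called members. With fewer than 5 genes called, the 10 genes of lowest p with a mean of at least 5 CPM were named too. Some genes that the rule names are not reported here.

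The fit was tested on simulated counts drawn from the means and library sizes of the rhMG53 against BSA comparison, with 13769 genes in each of 5 runs. It recovered 19.2% of genes changed 1.25-fold, 66.0% of those changed 1.5-fold, 82.0% of those changed 2-fold and 96.4% of those changed 3-fold. Of its calls 5.32% were false. Each fold was given to 250 genes over the 5 runs, many more changed genes than the 3 called in the data. The adjustment is stricter where fewer genes change, so these shares can overstate the recovery in the real comparison. Of simulated lists raised 1.1-fold, camera recovered 25 of 25 and called 0 of 135 unchanged lists, with genes drawn independently, which real genes are not.

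Alternatives were other scaling factors (RLE, upper quartile, library size alone), no filter on low counts beyond a total of at least 1, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom, robust moderation, a log2 fold change of at least 1 in size, an adjusted p under 0.01, the fit with the replicate number as a term, camera with an estimated correlation, the self-contained test fry, and leaving out each library in turn. Removing a loess trend of log2 CPM on transcript GC content and length (span 0.5) was added after the data were seen. It covered 94.1% of the tested genes. Total counts of 17374151 to 22738745 per library put the limit set by 3 counts at 0.132 to 0.173 CPM, for counting error only. Data were prepared and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.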

Results

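RNA was sequenced from primary muscle satellite cells, the stem cells of skeletal muscle, that had been isolated from the hindlimbs of wild-type C57BL/6 mice and that the labels call ageing, with no age given. The cells had been kept in growth medium with recombinant human MG53 (rhMG53) or with bovine serum albumin (BSA), the vehicle control, for 72 h. Both groups expressed genes of differentiated muscle at high levels, with sarcomere and contraction genes at 13.5% of counts with BSA and 13.2% with rhMG53. The results therefore describe cultures that held differentiated muscle cells, and not stem cells alone. MG53 is a TRIM family protein of striated muscle, encoded in the mouse by Trim72 and known for its part in the repair of the plasma membrane. Each group held 3 libraries. Total gene counts were 22738745, 17898768 and 18204493 in BSA replicates 1 to 3 and 19827476, 17972900 and 17374151 in rhMG53 replicates 1 to 3. The design text calls the replicates biological, but no label ties a library to an animal or a culture, so the p-values measure the spread between these libraries, part of which may be technical. The design implies a single comparison, rhMG53 against BSA, which asks which genes the added protein changes.

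Both metallothionein genes and the heme oxygenase gene were higher in all 3 rhMG53 libraries than in any BSA library. Mt2, which encodes a small cysteine-rich protein that binds zinc and copper, stood at 20.8 ± 1.43 CPM (counts scaled by library size) with BSA and 39.5 ± 3.88 CPM with rhMG53 (SD, n = 3 each), a 1.90-fold rise. Its paralog Mt1 went from 32.3 ± 1.64 to 58.5 ± 6.61 CPM, a 1.81-fold rise. Hmox1, the inducible enzyme that degrades heme, went from 97.3 ± 3.87 to 136.9 ± 6.18 CPM, a 1.41-fold rise. The log2 fold changes were 0.93 (SE 0.088, 95% interval 0.73 to 1.12) for Mt2, 0.86 (SE 0.087, interval 0.67 to 1.05) for Mt1 and 0.49 (SE 0.061, interval 0.36 to 0.63) for Hmox1. These were the only 3 of 13769 tested genes past the threshold in edgeR's quasi-likelihood test (adjusted p = 0.00629 for Mt2 and for Mt1, and 0.0313 for Hmox1). In mm10 all 3 lie on chromosome 8, Mt2 (gene ID 17750) at 94172618 to 94173567, Mt1 (17748) at 94178883 to 94180327 and Hmox1 (15368) at 75093618 to 75100593. Without BSA replicate 2 no gene passed, with adjusted p at 0.141 for Mt2 and 0.152 for Mt1, whose calls stood when any other library was left out. Hmox1 did not pass when any of the 6 libraries was left out (adjusted p 0.0685 to 0.571, log2 fold change 0.46 to 0.53). With the replicate number as a term in edgeR, no gene passed (adjusted p = 0.271 for Mt2 and for Mt1, and 0.294 for Hmox1). The log2 fold changes were then 0.92, 0.85 and 0.49, in a fit with fewer residual degrees of freedom.

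**Figure D1:**
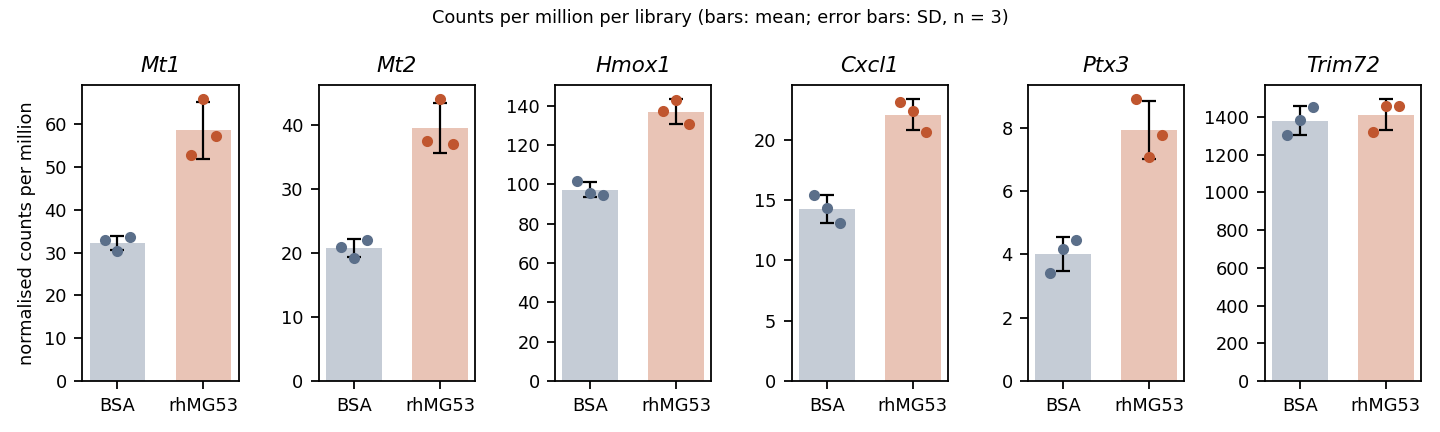
Normalised counts (CPM) of 6 genes in each library (points), with group means (bars, from 0) and SD (error bars, n = 3 per group). Mt1, Mt2 and Hmox1 are past the threshold, Cxcl1 and Ptx3 are not (adjusted p 0.0881 and 0.111), and Trim72 lies at 1380 CPM with BSA and 1411 CPM with rhMG53.

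No gene passed with lower counts in rhMG53. In edgeR 306 genes were lower at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0 lower genes, with 156 and 312 at an unadjusted p under 0.05. In both directions 716 genes had an unadjusted p under 0.05, against 688 expected by chance, and groups did not overlap in 10.8% of genes, against 10% by chance. The next genes by p among those with at least 5 CPM did not pass. Cxcl1, a neutrophil-attracting chemokine (chromosome 5, 90891245 to 90893121), was at 14.3 ± 1.17 CPM with BSA and 22.1 ± 1.28 CPM with rhMG53 (log2 fold change 0.62, SE 0.090, adjusted p = 0.0881). Ptx3, a secreted pattern recognition protein (chromosome 3, 66219887 to 66225806), was at 4.01 ± 0.545 and 7.91 ± 0.910 CPM (log2 fold change 0.99, SE 0.150, adjusted p = 0.111). DESeq2 called both, with adjusted p at 0.00110 for each. H1f3, a linker histone gene, had a log2 fold change of -0.58 (SE 0.104, adjusted p = 0.380). The dipeptidase gene Cndp2 (0.33), Gclm (0.45), the myelin gene Pmp22 (0.53) and 4930526I15Rik (0.57) had positive log2 fold changes and an adjusted p of 0.855.

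Antioxidant genes and targets of the transcription factor NRF2 rose as a group. Of the 33 measured members, 29 were higher and 4 lower, with a mean log2 fold change of 0.18 and a median of 0.13. The 3 called genes belong to this list, and 9 members passed when adjusted over the list alone. Besides Mt1, Mt2 and Hmox1 these were Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis (0.45, SE 0.0998), and 5 genes named after their values were seen. These 5 were the sulfiredoxin gene Srxn1 (0.37, SE 0.098), the quinone reductase gene Nqo1 (0.32, SE 0.089), the autophagy receptor gene Sqstm1 (0.23, SE 0.063), the thioredoxin reductase gene Txnrd1 (0.17, SE 0.058) and the peroxiredoxin gene Prdx6 (0.17, SE 0.057). The list passed limma camera with a preset correlation (adjusted p = 1.20e-08) and did not pass with a correlation estimated from the data (adjusted p = 0.294 with an estimated correlation).

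**Figure D2:**
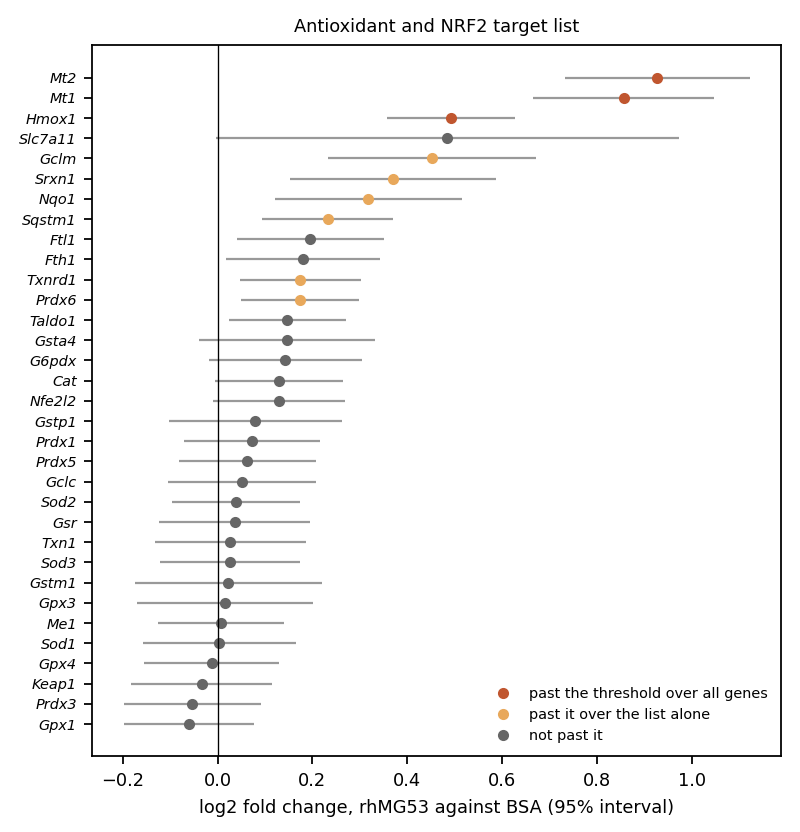
Log2 fold change, rhMG53 against BSA, of each of the 33 measured members of the antioxidant and NRF2 target list (points), with 95% intervals (lines), 3 libraries per group. Mt2, Mt1 and Hmox1 are past the threshold over all genes, 6 others pass over the list alone, and 4 members lie below 0.

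Secreted factors of senescent cells and NF-kB target genes rose as groups. In the secreted factor list 34 of 42 members were higher, with a median log2 fold change of 0.10, and in the NF-kB list 27 of 31, with a median of 0.09, and the lists share 9 members. No member passed over all genes in edgeR, where 10 and 6 members had an unadjusted p under 0.05, while DESeq2 called Cxcl1. Adjusted over the list alone, Cxcl1 passed in both lists, and the matrix metalloproteinase gene Mmp3 (0.37, SE 0.101) and the macrophage growth factor gene Csf1 (0.27, SE 0.076) passed in the NF-kB list. Csf1 was at 295.7 ± 23.9 CPM with BSA and 356.9 ± 25.4 CPM with rhMG53. The chemokine gene Cxcl5 (0.66, SE 0.204) and Igfbp7, which encodes a secreted binding protein (0.28, SE 0.085), did not pass in any list. Camera gave an adjusted p of 1.24e-05 for the secreted factors and 2.08e-04 for the NF-kB list, and with an estimated correlation the adjusted p was 0.429 and 0.294. Both calls stood when each library was left out in turn. The markers of macrophages and other leukocytes summed to 18.0 ± 1.28 CPM with BSA and 18.7 ± 3.30 CPM with rhMG53.

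The CDK inhibitor and senescence marker list and the TGF-beta response list also passed camera with the preset correlation. In the former 14 of 21 members were higher (median log2 fold change 0.09, adjusted p = 0.0350, and adjusted p = 0.607 with an estimated correlation). That list was not sorted by the direction its members take in senescence, so its rise does not measure senescence. Its members with the smallest p were Tgfb1 (0.26, SE 0.097), Cdkn2a (0.17, SE 0.070), the lysosomal glycoprotein gene Gpnmb (0.19, SE 0.084) and Hmga2, a chromatin architecture gene (0.15, SE 0.070), with 0 passing over all genes or adjusted over the list alone in edgeR and 3 at an unadjusted p under 0.05. This call ended without BSA replicate 1 (adjusted p = 0.0811), BSA replicate 2 (0.305), rhMG53 replicate 2 (0.363) or rhMG53 replicate 3 (0.0809), with upper quartile factors (0.0521) and with the trend with GC content and length removed (0.102). Of the TGF-beta list 20 of 29 members were higher (median 0.06, adjusted p = 0.00786, and adjusted p = 0.443 with an estimated correlation), among them Tgfb2 (0.17, SE 0.057), Tgfb1 and, at 1.67 CPM, Tgfbi (0.49, SE 0.201). No TGF-beta list member passed in edgeR over all genes or over the list alone, and 5 had an unadjusted p under 0.05. The call ended without BSA replicate 2 (adjusted p = 0.141) or rhMG53 replicate 3 (0.0668).

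Interferon response genes had the largest mean shift of the called lists, at low levels. Of 37 members 31 were higher (mean log2 fold change 0.24, median 0.25, camera adjusted p = 4.55e-05, and adjusted p = 0.519 with an estimated correlation), and the median member stood at 3.06 CPM. The antiviral genes Cmpk2 (0.94, SE 0.302), Ifit1 (0.91, SE 0.297) and Oasl2 (1.13, SE 0.447) and the peptide transporter gene Tap1 (0.37, SE 0.143) did not pass. Oasl2 was at 1.82, 1.36 and 4.52 CPM in rhMG53 replicates 1 to 3 and at 1.18 ± 0.426 CPM with BSA. Without rhMG53 replicate 3 the list did not pass (adjusted p = 0.0809), nor did it among genes with at least 5 CPM (0.0589). The unnamed gene ID 100861531 took 0.902% of counts in rhMG53 replicate 3, against 0.226% to 0.327% with BSA. It also took 0.563% in rhMG53 replicate 2, without which the list still passed.

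The cholesterol synthesis list passed camera with the preset correlation, 23 of 25 members being higher with a median log2 fold change of 0.08 (adjusted p = 0.00121, and adjusted p = 0.519 with an estimated correlation). Insig1, a sterol-sensing regulator of the pathway, was at 119.0 ± 1.88 CPM with BSA and 137.9 ± 5.53 CPM with rhMG53 (0.21, SE 0.057), and the enzyme genes Mvd and Sqle had log2 fold changes of 0.14 and 0.14, with adjusted p at 0.935 to 0.950 for these 3. The list did not pass without rhMG53 replicate 3 (adjusted p = 0.0809). Of the unfolded protein and integrated stress response list 27 of 36 members were higher (median 0.04, adjusted p = 0.0318, and adjusted p = 0.519 with an estimated correlation). Those with the smallest p were the amino acid transporter genes Slc3a2 (0.18, SE 0.061) and Slc7a11 (0.48, SE 0.222), Sesn2 (0.23, SE 0.086) and the pseudokinase gene Trib3 (0.39, SE 0.175), of which none passed. That call ended without BSA replicate 2 (0.114), BSA replicate 3 (0.0856), rhMG53 replicate 1 (0.113) or rhMG53 replicate 2 (0.140), and with the trend with GC content and length removed (0.0839). Cytosolic ribosomal protein genes were higher in 57 of 67 cases (median 0.03, adjusted p = 0.0121, and adjusted p = 0.871 with an estimated correlation), with Rpl13 at 0.53 (SE 0.159), Rps2 at 0.25 (SE 0.085), Rps29 at 0.16 (SE 0.075) and Rpl29 at 0.12 (SE 0.067). Ribosomal protein genes have many processed pseudogenes that can share their reads. The ribosomal call ended without BSA replicate 1 (0.0831) or BSA replicate 3 (0.0856), ended when the trend with GC content and length was removed (0.797), and turned to the opposite direction without rhMG53 replicate 2 (0.259).

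**Figure D3:**
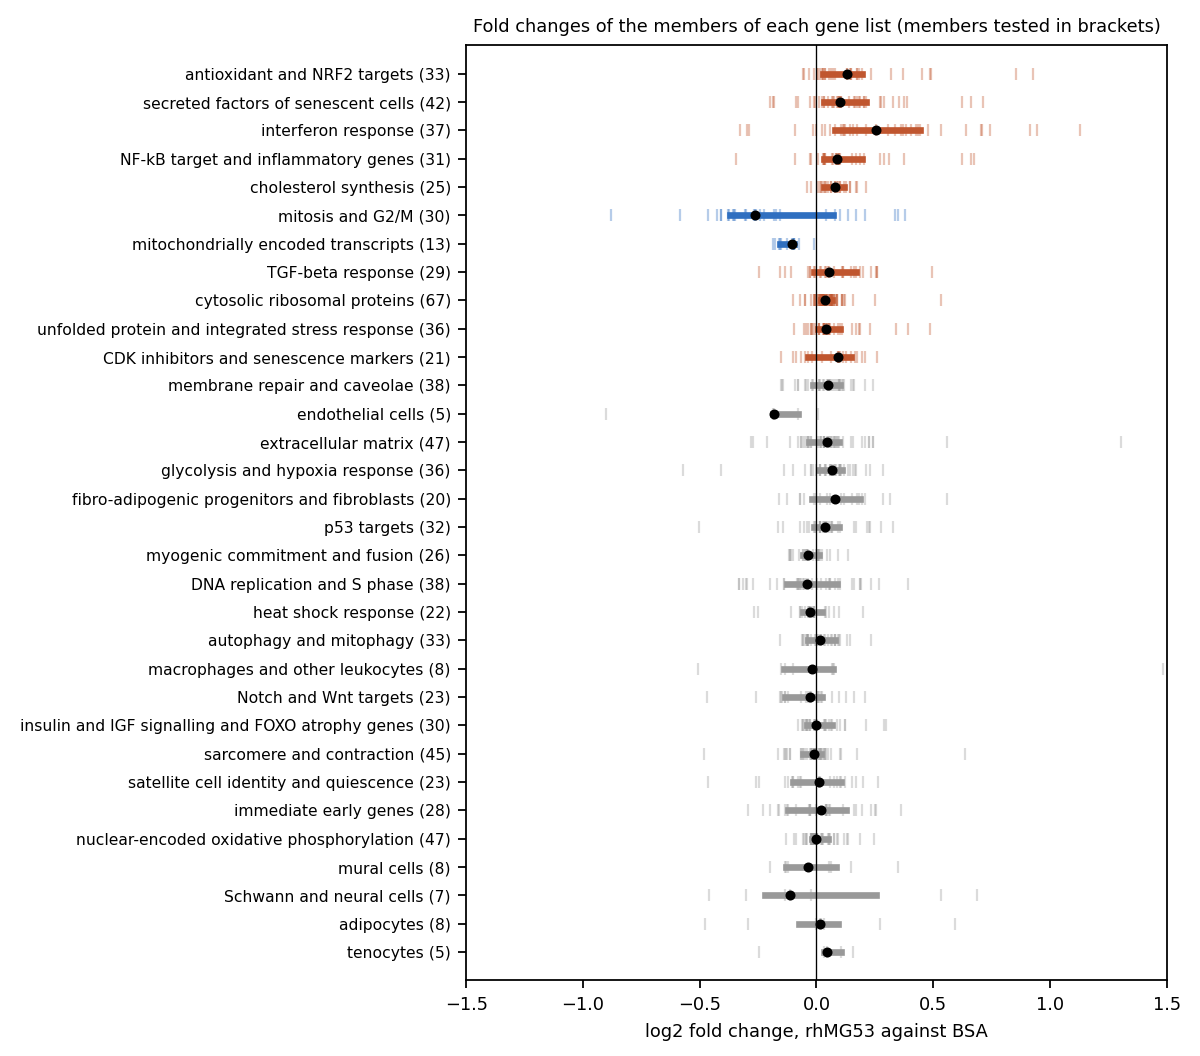
Log2 fold change, rhMG53 against BSA, of the members of each of the 32 tested gene lists (ticks), with the median (point) and the range from the lower to the upper quartile (bar), and the number of members in brackets. Lists past camera's threshold with a preset correlation are coloured, 9 upward in orange and 2 downward in blue, and 0 pass with an estimated correlation, where 3 had an unadjusted p under 0.05.

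Mitosis and G2/M genes were lower as a group, in cells that expressed little of them. Of 30 measured members 21 were lower and 9 higher, with a median log2 fold change of -0.26 and a median level of 1.29 CPM (adjusted p = 0.00128, and adjusted p = 0.294 with an estimated correlation). With members too low to test included, the list summed to 59.4 ± 0.167 CPM with BSA and 53.3 ± 1.72 CPM with rhMG53. The exact permutation p was 0.1, the smallest that 3 against 3 can give. The BSA SD is smaller than the counting error of such a sum, so it understates the spread. The kinetochore motor gene Cenpe (-0.88, SE 0.325), Ect2, needed for cytokinesis (-0.58, SE 0.244), and the ubiquitin-conjugating enzyme gene Ube2c (-0.46, SE 0.233) had negative log2 fold changes, while Cenpf, another kinetochore gene, had a positive one (0.35, SE 0.154), and none of the 4 passed. The call stood when each library was left out in turn. The DNA replication and S phase list, with 21 of 38 members lower and a median of -0.03, did not pass (adjusted p = 0.309).

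All 13 measured mitochondrially encoded transcripts were lower, with a median log2 fold change of -0.11 (adjusted p = 0.00753, and adjusted p = 0.687 with an estimated correlation). The 4 with the smallest p, mt-Nd4l (-0.19), mt-Nd5 (-0.18), mt-Co1 (-0.16) and mt-Nd4 (-0.16), had an adjusted p of 0.965 to 0.973. Their genes took 7.28 ± 0.844% of counts with BSA and 6.70 ± 0.799% with rhMG53, a difference smaller than the spread (exact permutation p = 0.5). BSA replicate 3 had the highest share, 8.19%, and rhMG53 replicate 3 the lowest, 5.78%, and the call ended without either (adjusted p = 0.420 and 0.528). No member of the interferon, cholesterol, stress response, ribosomal protein, mitosis or mitochondrial lists passed in edgeR over all genes or adjusted over the list alone, with 7, 3, 3, 2, 3 and 0 members at an unadjusted p under 0.05. Nuclear-encoded oxidative phosphorylation genes did not pass (21 higher, 26 lower, adjusted p = 0.799).

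The genes that mark stages of muscle differentiation did not pass in either direction. Trim72 (gene ID 434246, chromosome 7, 128003462 to 128011393) was at 1380 ± 74.5 CPM with BSA and 1411 ± 80.8 CPM with rhMG53, a log2 fold change of 0.03 with a 95% interval of -0.12 to 0.19 (adjusted p = 0.992). These counts measure the cells' own transcript and not the added human protein. The myogenic regulators Myod1 (443.0 CPM over all libraries) and Myog (910.1 CPM) had log2 fold changes of -0.04 (interval -0.19 to 0.11) and 0.05 (interval -0.10 to 0.19). The satellite cell factor Pax7, at 9.24 CPM, had a log2 fold change of -0.25 (interval -0.54 to 0.05), and Myf5, at 15.3 CPM, one of 0.06 (interval -0.12 to 0.23). Embryonic myosin heavy chain, Myh3, was at 22392 ± 464.7 CPM with BSA and 20527 ± 2556 CPM with rhMG53 (-0.13, interval -0.34 to 0.09). The 45 sarcomere and contraction genes took 13.5 ± 0.221% of counts with BSA and 13.2 ± 0.548% with rhMG53, and the proliferation marker Mki67 stood at 1.1 CPM. The log2 fold changes of the cell cycle inhibitor genes were 0.06 (interval -0.08 to 0.21) for Cdkn1a, at 2115 CPM, and 0.17 (interval 0.01 to 0.32, adjusted p = 0.950) for Cdkn2a. The collagen gene Col1a1 (0.08, interval -0.13 to 0.30) and the insulin receptor substrate gene Irs1 (-0.04, interval -0.23 to 0.15) did not pass. The signs for Trim72, Myod1, Myog, Col1a1 and Irs1 turned under at least 1 alternative.

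**Figure D4:**
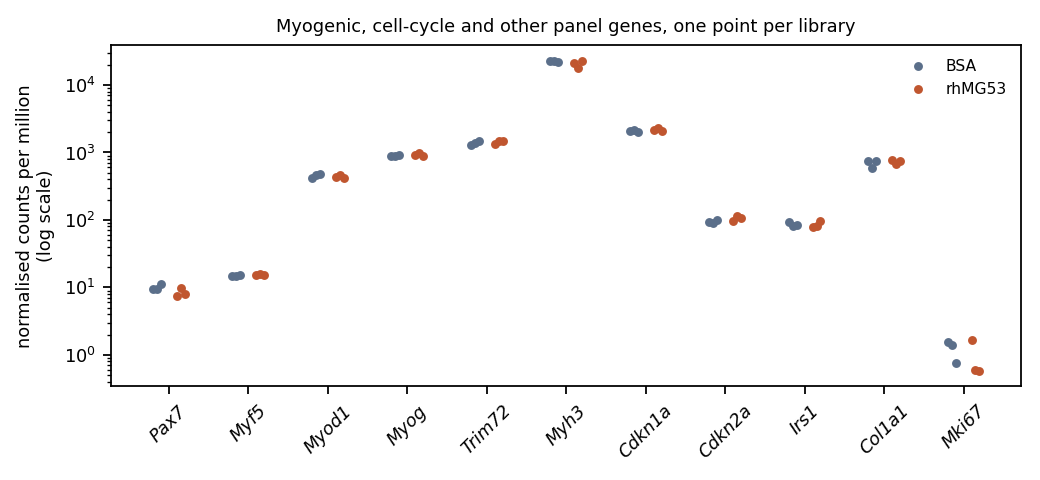
Normalised counts (CPM), on a log scale, of the 10 panel genes and Trim72 in each library (points, 3 per group). The means run from 1.1 CPM for Mki67, whose libraries spread widely (0.770 to 1.55 CPM with BSA and 0.580 to 1.67 CPM with rhMG53), to 21460 CPM for Myh3.

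The remaining process lists did not pass, although extracellular matrix, glycolysis and hypoxia response, p53 targets and membrane repair passed under 5, 4, 1 and 1 of the alternatives, and oxidative phosphorylation under 1. Adjusted p was 0.0554 for membrane repair and caveolae (27 of 38 members higher, median log2 fold change 0.05), 0.0634 for extracellular matrix and for glycolysis and hypoxia response, 0.102 for p53 targets, 0.304 for myogenic commitment and fusion, 0.337 for heat shock response and 0.450 for autophagy and mitophagy. It was 0.583 for Notch and Wnt targets, 0.629 for insulin and IGF signalling with FOXO atrophy genes, 0.665 for sarcomere and contraction, 0.676 for satellite cell identity and quiescence and 0.700 for immediate early genes. No member of these lists passed in edgeR over all genes or adjusted over the list alone, with 0 to 6 members of each at an unadjusted p under 0.05.

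Markers of other cell types that a muscle preparation can hold did not pass in this fit, although the fibro-adipogenic and fibroblast list passed, upward, without BSA replicate 1 (adjusted p = 0.0437), BSA replicate 3 (0.0146) or rhMG53 replicate 2 (0.0210), and the endothelial list passed, downward, with library size scaling (0.0438). Adjusted p was 0.0554 for endothelial cells (4 of 5 members lower), 0.0797 for fibro-adipogenic progenitors and fibroblasts, 0.583 for leukocytes, 0.799 for mural and for Schwann and neural cells, 0.914 for adipocytes and 0.956 for tenocytes. Adjusted over the list alone, Pmp22 passed among the Schwann cell markers and, named after its value was seen, the lipase gene Lpl among the adipocyte markers (-0.48, SE 0.111). The red blood cell markers were too low to test, at 0.169 CPM with BSA and 0.150 CPM with rhMG53 in sum. The median, the mean and the test differed in sign for satellite cell identity, oxidative phosphorylation, mural cells, Schwann cells, adipocytes and tenocytes.

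Exact permutation tests of library measures cannot give a p below 0.1 with 3 against 3. The share of counts in the 10 most abundant genes reached that smallest p (exact permutation p = 0.1), at 11.5% to 12.4% in the BSA libraries and 11.3% to 11.4% in the rhMG53 libraries. Total counts, detected genes and the share in ribosomal protein genes overlapped between the groups (exact permutation p 0.4 to 0.6). The gene with the ID 100861531, which the tables used here do not name and which was chosen after its values were seen, took 0.563% and 0.902% of counts in rhMG53 replicates 2 and 3 and 0.226% to 0.327% in the other 4 libraries. Of the 13769 tested genes 79.0% had a 95% interval within a 1.5-fold change in both directions. Mt1 and Mt2 are close paralogs and how the counting treated shared reads is not given, so the split of counts between them is uncertain.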

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

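The removal of the GC content and length trend was chosen after the data were seen, and the other alternatives were fixed beforehand. The count of 3 genes stayed at 3 with RLE, upper quartile or library size scaling, with a mean of at least 5 CPM and in limma voom, was 2 at an adjusted p under 0.01, and rose to 4 with robust moderation and with the GC content and length trend removed, Cxcl1 being the added gene. It was 6 with no filter on low counts (Cxcl1, Ptx3 and the unnamed ID 100628626, named after its values were seen, added) and 5 in the DESeq2 Wald test (Cxcl1 and Ptx3 added). No gene passed with an absolute log2 fold change of at least 1 as well, a count of 0, since none of the 3 genes reached that size. Leaving out each library gave 0 to 4 genes: 0 without BSA replicate 2, where 518 genes had an unadjusted p under 0.05 in edgeR, 2 without BSA replicate 1, BSA replicate 3, rhMG53 replicate 2 or rhMG53 replicate 3, and 4 without rhMG53 replicate 1, the added genes being Rn7sk and the unnamed ID 19791, both named here after their values were seen. Fewer libraries also give the test less power. With the replicate block the count was 0 in edgeR, with 609 genes at an unadjusted p under 0.05 and log2 fold changes of 0.92 for Mt2, 0.85 for Mt1 and 0.49 for Hmox1, and 13 lists passed. The block leaves fewer residual degrees of freedom, and whether the numbers pair samples is unknown. With 3 libraries per group, same-number correlations of deviations (0.19, -0.13 and -0.15, own number best in 2 of 6 libraries) cannot decide.

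The count of 11 lists was 9 to 13 under the other scalings, filters, the block and the trend removal. It was 0 with an estimated inter-gene correlation (3 lists at an unadjusted p under 0.05) and 0 in fry's directional test (8 at an unadjusted p under 0.05), where the smallest adjusted p was 0.0639, for the antioxidant and the mitosis lists. Fry's test for change in either direction called 6 lists. Leaving out each library gave 6 to 12 lists, 6 without rhMG53 replicate 3. The antioxidant, mitosis, NF-kB and secreted factor lists kept their calls in all 6 of these fits, and the 11 lists together kept them in 120 of 164 alternatives. Lists that did not pass gained a call, in the same direction, 17 times: extracellular matrix 5 times (lowest adjusted p 3.74e-05, without rhMG53 replicate 2), glycolysis and hypoxia response 4 times (4.39e-06, without BSA replicate 3), fibro-adipogenic progenitors and fibroblasts 3 times (0.0146, without BSA replicate 3), endothelial cells 2 times (0.0438 with library size alone and 0.0401 with the block), and once each p53 targets (0.0254, without BSA replicate 1), membrane repair (0.0438, library size alone) and oxidative phosphorylation (0.0192, without rhMG53 replicate 1).

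Direction turned in the cases below, given as adjusted p, and the cause was not tested. None passed where its direction was opposite, and ribosomal proteins, without rhMG53 replicate 2, were the only list among them called with all libraries. With the GC content and length trend removed these were oxidative phosphorylation (0.171) and tenocytes (0.9753). With no filter they were tenocytes (0.475), mural cells (0.568) and leukocytes (0.503). Notch and Wnt targets turned at a mean of at least 5 CPM (0.886), and tenocytes with upper quartile factors (0.984) and in fry (0.940). Leaving out at least 1 of the libraries turned the following lists, whose adjusted p over all 6 such fits, turned or not, ranged from 0.521 to 0.917 for Schwann cells, 0.456 to 0.969 for adipocytes, 9.73e-05 to 0.259 for ribosomal proteins, 4.39e-06 to 0.996 for glycolysis and hypoxia, 0.130 to 0.951 for immediate early genes, 0.123 to 0.931 for insulin and IGF signalling, 0.305 to 0.787 for leukocytes, 0.391 to 0.990 for mural cells, 0.0192 to 0.856 for oxidative phosphorylation, 0.0809 to 0.969 for the sarcomere and 0.296 to 0.956 for tenocytes. Log2 fold changes then ranged from -0.0261 to 0.146 for Col1a1, -0.130 to 0.0261 for Irs1, -0.0903 to 0.000299 for Myod1, -0.00972 to 0.0819 for Myog and -0.00488 to 0.0785 for Trim72. With the trend removed they were -0.00246 for Trim72 and 0.000360 for Irs1. The rhMG53 minus BSA difference ranged from -2080110 to 339878 in total counts and from -0.00573 to 0.145 percentage points in ribosomal protein share. Genes near the limit of 0.132 to 0.173 CPM set by 3 counts can show only large changes.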

Other observations

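The tests of a broader NRF2-type response, of leukocytes, of endotoxin and of dividing cells, and the removal of the GC content and length trend, were chosen after the result each one measures had been seen. Xist, Ddx3y, Itgam and the unnamed ID 19791 were also named after their values were seen.

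The largest differences between libraries did not follow treatment. The first principal component, 31.2% of the variance, set BSA replicate 3 (12.7) and rhMG53 replicate 2 (22.2) apart from the other 4 libraries (-11.4 to -6.18), and the second, 22.3%, put the BSA libraries at -14.2 to -6.49 and the rhMG53 libraries at 3.48 to 17.7. All 6 libraries held 0 counts of Xist, which allows up to 0.132 to 0.173 CPM, and 92.0 to 108.3 CPM of the Y-linked gene Ddx3y. The unnamed ID 19791 was at 219.8 and 343.8 CPM in rhMG53 replicates 2 and 3 and at 70.8 to 117.2 CPM in the other 4 libraries.

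Among the 10 splits of the 6 libraries into 3 and 3, the real one called 3 genes and the highest of the others 0, so that 1 split gave as many. For lists the real split called 11 and the highest other 12, and 2 splits gave as many as the real one. Splits this few cannot give a share under 0.05. The split of BSA replicates 1 and 2 and rhMG53 replicate 1 against the rest had 1872 genes at an unadjusted p under 0.05 against 716 in the real split, with 0 called, which points to a structure of the samples other than treatment. For the antioxidant, NF-kB, secreted factor, TGF-beta and mitosis lists the real split had the smallest camera p of the 10. The smallest p of another split came close for the secreted factors (1.41e-06 against 7.73e-07) and for TGF-beta (0.00541 against 0.00197), and lay further off for the antioxidant (0.00146 against 3.75e-10), NF-kB (0.000985 against 2.61e-05) and mitosis lists (0.0184 against 0.000240). The number of splits with a p as small, the real one included, was 2 for the cholesterol, stress response and CDK inhibitor lists, 3 for interferon, 4 for the mitochondrial list and 8 for ribosomal proteins. For interferon another split had a camera p of 1.63e-08 and a mean shift of 0.36 on the log2 scale, against 0.24 in the real one.

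The higher Mt1, Mt2 and Hmox1 in rhMG53 libraries kept a mean log2 fold change of 0.71 (SE 0.036) against 0.76 before the trend with GC content and length was removed, which argues against that trend as the whole cause. A load of metal sensed by the transcription factor MTF1 is a candidate explanation that stays open, since the MTF1 target Slc30a1 had a log2 fold change of 0.19 with a 95% interval of -0.05 to 0.43. A broader NRF2-type response stays open. The other 30 members of the antioxidant list, 26 of them higher, had a mean log2 fold change of 0.12. Their camera p with an estimated correlation was 0.0303, unadjusted. In the same test the whole list had an unadjusted p of 0.0202 and an adjusted p of 0.294. The members had been seen to rise before this test was chosen, so its p cannot decide. Zinc carried with the recombinant protein and an effect of the protein itself were not told apart by any value here.

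The higher NF-kB and secreted factor lists could come from leukocytes in the rhMG53 cultures, which stays open, since the leukocyte marker sum differed from the BSA mean by -2.62 to 3.98 CPM in the rhMG53 libraries, with a BSA SD of 1.28 CPM, and the Cxcl1 content of such cells is not known here. The most abundant of these markers, Itgam, stood at 4.85 CPM. Bacterial endotoxin in the recombinant protein stays open as well. All 12 measured genes of a panel of endotoxin-responsive genes belong to the NF-kB list itself, so that their directional p in fry, 0.0997, cannot decide for or against it. An effect of the protein itself was not tested apart from these.

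For the lower mitosis list, chance movement of low-count genes stays open. Among its 19 members with at least 1 CPM 16 were lower, with a median log2 fold change of -0.31. Their camera p was 1.97e-05 (0.00975 with an estimated correlation), both unadjusted. The test reused the same libraries on genes that were mostly still low, so it cannot decide. Its members above 5 CPM, Cenpf (5.38 CPM, log2 fold change 0.35) and Racgap1 (6.62 CPM, 0.04), were not lower. Fewer dividing cells in the rhMG53 cultures stay open, since the DNA replication and S phase list had a camera p of 0.184, which does not show that it did not fall. A change in the genes per dividing cell was not tested, and no gene of the list passed by itself.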
